A study of Mus musculus with 8 samples.

How the data were processed

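RNA was sequenced from forebrains of mouse embryos at E15.5, in 4 libraries labelled Het and 4 labelled KO for Baf53a, the protein encoded by Actl6a and a subunit of BAF chromatin remodelling complexes. Per the labels' protocols, the forebrains were dissociated to single cells, and stranded SMARTer libraries were made from total RNA after removal of ribosomal RNA. The submitters' processing notes list cutadapt 1.16, kallisto without a version, and the mouse build mm10.

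The deposited estimated counts are kallisto's assignment of reads to transcripts, and each of the 8 deposited tables lists 63814 transcripts under UCSC known-gene identifiers. The authors also deposited TPM values, which divide the estimated counts by effective transcript length and scale each library to the same total. Effective lengths were identical in all 8 libraries, so length-scaled TPM returned the estimated counts to within 0.000939%. The estimates carry no measure of how uncertain the assignment of a read to one of several isoforms was.

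The files do not pair the transcript identifiers with gene names. A search of the 12 reference files used here found 0 of the identifiers. Counts could therefore not be summed per gene, which was the design fixed before the data were examined. The level of Actl6a, and with it a check of the genotype labels, the BAF subunits and 39 lists of marker and pathway genes are not analysed here. The comparison of transcripts, set down beforehand as an alternative, took the place of the comparison of genes.

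Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, using its default expression filter, TMM factors, robust dispersion estimates and the quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Standard errors are the size of the log2 fold change divided by the square root of the F statistic. Log2 CPM used a prior count of 2. Named transcripts are the 2 with the largest rise and the 2 with the largest fall among those called, with a mean log2 CPM of at least 2 and group ranges that did not overlap. The rule as fixed took 10 in each direction and was shortened because the identifiers carry no gene names.

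A second comparison was chosen after the transcript results had been seen. Runs of up to 40 neighbouring transcripts whose estimates summed to whole reads in every informative library, within the rounding of the deposited digits and at most 0.15 counts, were taken as sets that share reads only among themselves. At least 4 libraries had to be informative. The search found 6682 sets of several transcripts, against 43 after the order of the transcripts was shuffled. Sets and single transcripts with whole estimates are called read-sharing units; they are not genes. They held 41.9% of all estimated counts, while 16594 detected transcripts lay in no such unit. Single transcripts with whole estimates are described below as sharing no reads, which is inferred. An isoform that shared their reads but was given no counts would leave whole estimates too. On simulated data, 100% of 1662 loci with several transcripts were recovered. All simulated loci were runs of neighbours that shared no reads with other loci. The simulation therefore checks the search alone, and not loci that share reads with distant transcripts.

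The edgeR step was tested on counts simulated from the means, library sizes and dispersions of these libraries, in 5 draws. Changes were placed only on features with a mean CPM of at least 2. Over the 5 draws 489 transcripts changed 2-fold and 489 changed 4-fold passed the expression filter, and among units 494 and 496 did. Changed features lost to the filter do not enter the recovery. Recovery of changes in less abundant features, or where a larger share of features changed, was not tested. Among 29370 simulated transcripts, 23.7% of those changed 2-fold and 62.8% of those changed 4-fold were recovered, and 4.94% of calls were false, from 2.25% to 7.34% per draw. Among 9280 simulated units, 90.9% of those changed 2-fold and 99.2% of those changed 4-fold were recovered, and 5.43% of calls were false, from 3.54% to 7.28% per draw. The number of draws was raised to 5 after a first single draw of each, in which 9.77% of unit calls and 2.25% of transcript calls were false.

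Totals per library ran from 10707086 to 19561022 estimated counts. Depth and composition were compared by exact two-sided permutation tests over 70 arrangements, for which the smallest p is 0.0286, with adjustment over the measures compared. Thinning to equal depth drew 10706899 counts from each library. Alternatives used DESeq2 1.42.0, limma 3.58.1, other scaling factors and filters, log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, and each library left out. The labels do not say that the libraries came from separate embryos or litters, so p-values measure the spread between these libraries, which may be partly technical.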

Results

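The series compared forebrains of Baf53a Het and Baf53a KO mouse embryos at E15.5, with 4 libraries per genotype, to ask which transcripts differ when this BAF subunit is lost from the developing brain. The Het libraries held 13535246, 13188649, 13819586 and 10707086 estimated counts and the KO libraries 14644825, 19561022, 13659903 and 16085582. No pair of replicates agreed within counting noise, which leaves out variation from library preparation: the chi-square per degree of freedom lay between 4.84 and 9.73 over read-sharing units.

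Of 29370 transcripts tested, 485 were higher and 289 lower in KO than in Het at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Most changes were below 2-fold: 164 of the transcripts that rose and 57 of those that fell changed by more, and 53 and 10 changed by more than 4-fold. The median rise was 0.79 and the median fall -0.60 on the log2 scale. All 774 had group ranges of log2 CPM that did not overlap, as did 14.3% of all tested transcripts, where chance gives 2.86%. The count fell whichever library was left out, with fewer samples in each fit. It was 123, 454, 70 and 136 without Het 1, 2, 3 and 4 in turn, and 125, 94, 281 and 60 without KO 1, 2, 3 and 4. It also moved to 3574 with DESeq2, 391 without a filter on low counts, 188 with a covariate derived from the data, and 35 or 16 with limma on log2(TPM + 1) or log2(TPM + 0.1). With the replicate number as a block it was 0 (4684 at an unadjusted edgeR p under 0.05), though the numbers were not taken to pair samples.

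The transcript uc007gqv.3, of 7125 bases, had the largest rise under the naming rule. Its log2 CPM was 0.92 ± 0.50 (SD, n = 4) in Het and 3.59 ± 0.53 (SD, n = 4) in KO, a log2 fold change of 2.76 (SE 0.38, edgeR adjusted p = 0.0213). The transcript uc009phk.1 rose by 2.53 (SE 0.25, edgeR adjusted p = 0.00804), from 29.2 to 58.1 estimated counts in the Het libraries to 260.1 to 343.7 in the KO libraries. Both share reads with other transcripts and lie in no closed set, so their estimates depend on how reads were assigned. The transcript uc008iog.1 had whole estimates in every library, which was read as sharing no reads with another. It held 134, 110, 125 and 76 counts in Het and 33, 43, 20 and 26 in KO, a log2 fold change of -2.22 (SE 0.22, edgeR adjusted p = 0.00817). The transcript uc007jqz.2 had a log2 fold change of -1.97 (SE 0.30, edgeR adjusted p = 0.0258). It forms a set with 1 neighbour, and the set of 2 as a whole fell less, with a log2 fold change of -0.47 (SE 0.07, edgeR adjusted p = 0.000151). The call of uc007gqv.3 was lost without Het 3, Het 4, KO 1 or KO 4, at edgeR adjusted p of 0.0658, 0.0655, 0.0557 and 0.0638. The call of uc007jqz.2 was lost without Het 1, Het 3, Het 4, KO 1, KO 2 or KO 4, at edgeR adjusted p of 0.0679, 0.0655, 0.0683, 0.065, 0.0922 and 0.0789. It was also lost with limma on log2(TPM + 1) or log2(TPM + 0.1), at limma adjusted p of 0.126 and 0.204, and with the data-derived covariate, at edgeR adjusted p of 0.0569. The call of uc007gqv.3 was lost with limma on log2(TPM + 0.1), at a limma adjusted p of 0.0588. With the replicate number as a block all 4 calls were lost. The edgeR adjusted p was then 0.124 for uc007gqv.3, uc009phk.1 and uc008iog.1 and 0.111 for uc007jqz.2. On the log2(TPM + 1) scale, which understates changes of low transcripts, the fold change of uc007gqv.3 was 1.18 and that of uc008iog.1 was -1.41.

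**Figure D1:**
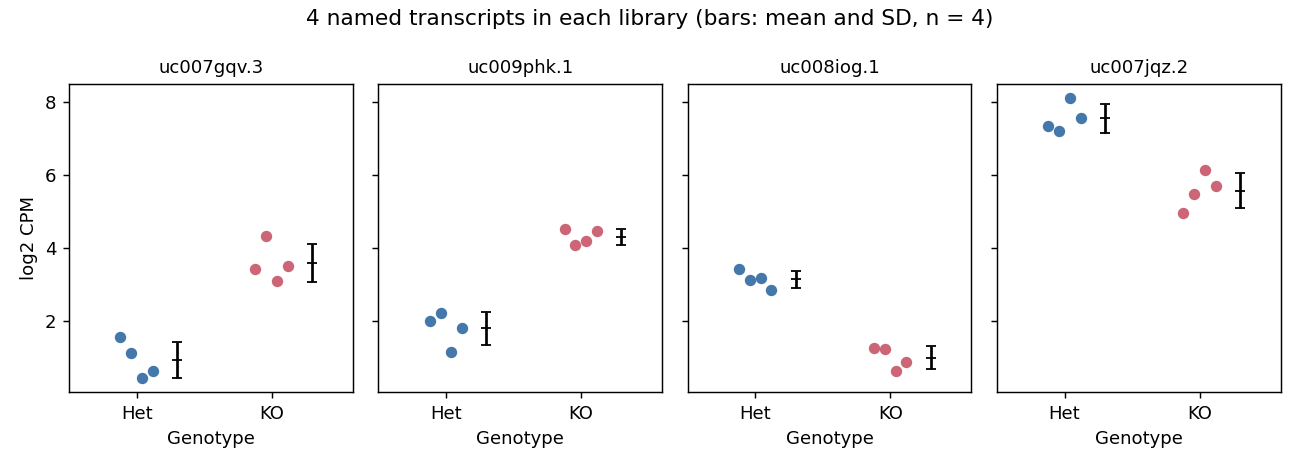
Log2 CPM (vertical axis) of the 4 named transcripts in each Het and KO library (horizontal axis), 1 point per library, with the mean and SD of each genotype as a black mark and bar (n = 4). The Het and KO points do not overlap in any of the 4 panels, which the naming rule required.

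Reads that isoforms share were then counted once per read-sharing unit, a comparison chosen after the transcript results were seen. Of 9280 units tested, 1200 were higher and 1076 lower in KO (edgeR, adjusted p under 0.05), or 24.5% of units against 2.64% of transcripts. Single transcripts that share no reads have the same counts in both fits, yet 4.99% of them were called when fitted with all transcripts and 22.9% when fitted with units, so the share called also depended on which rows were fitted together. Among sets of several transcripts, 753 rose and 751 fell of 5914 tested. Among single transcripts that share no reads, 447 rose and 325 fell of 3366 tested. Changes were small, with a median rise of 0.61 and a median fall of -0.43 on the log2 scale, and 253 units rose and 90 fell by more than 2-fold. In 1257 of the 1504 called sets no member transcript was called by itself. All 168 single transcripts called in the transcript test were called in the same direction as units, as were the sets of 263 of 290 called member transcripts; the sets of the other 27 were not called. When the other transcripts were fitted beside the units, 1258 units were called, 788 higher and 470 lower, of which 1245 were among the 2276. Units cover 41.9% of the counts, so these numbers say nothing of the remaining transcripts.

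The first principal component of the 500 most variable transcripts held 18.0% of their variance and did not separate the genotypes. For units it held 54.6%, with Het scores from -16.9 to -11.1 and KO scores from 11.3 to 16.6.

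**Figure D2:**
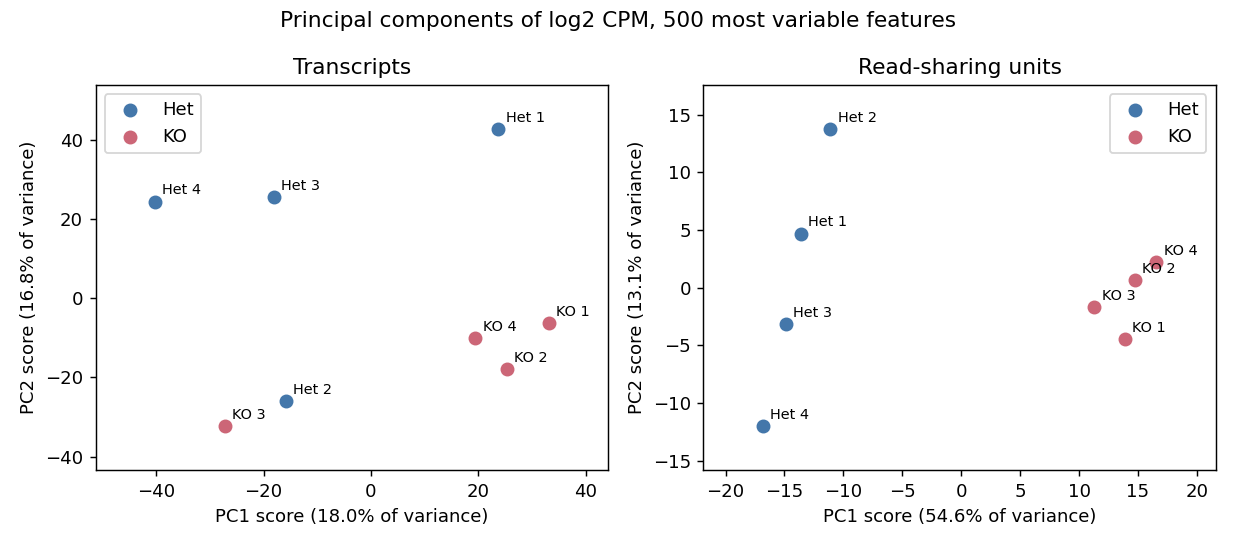
Scores of the 8 libraries on the first (horizontal axis) and second (vertical axis) principal components of log2 CPM, for transcripts on the left and read-sharing units on the right, 1 point per library and 1 colour per genotype. Het and KO libraries overlap along the first component for transcripts and lie apart for units.

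**Figure D3:**
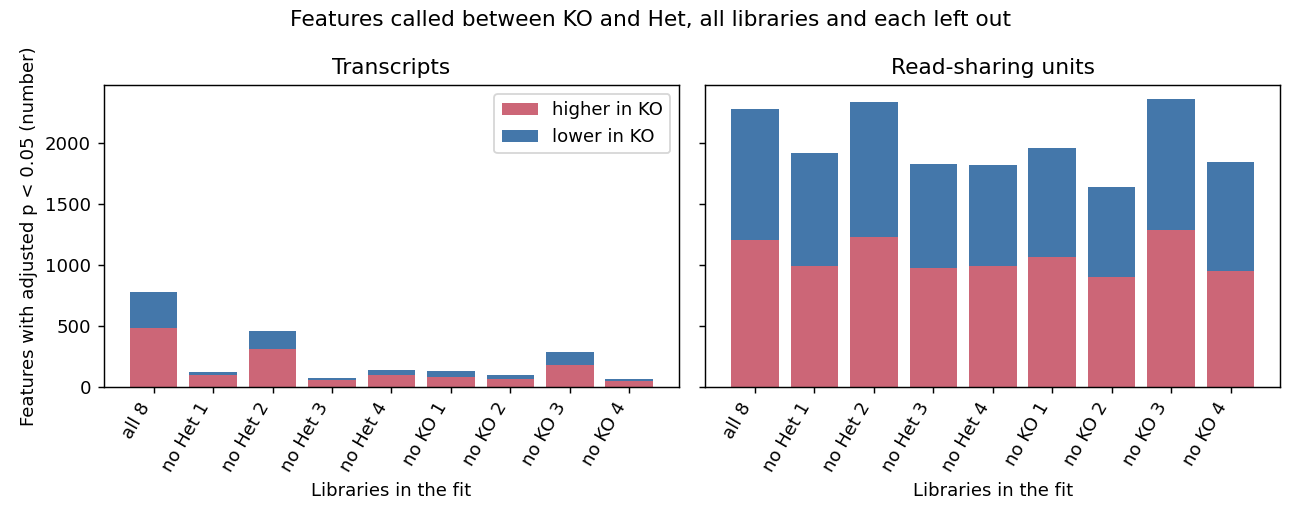
Number of features called at an adjusted p under 0.05 (vertical axis) with all 8 libraries and with each library left out (horizontal axis), stacked by direction in KO. Transcript calls fell from 774 to between 60 and 454, and unit calls lay between 1642 and 2359 against 2276.

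KO libraries held 15987800 ± 2582000 estimated counts and Het libraries 12812600 ± 1427220 (SD, n = 4), a ratio of 1.25 that missed the threshold (exact two-sided permutation p = 0.0571, adjusted 0.0952). At equal depth, 36251 ± 319 transcripts had at least 1 count in KO and 34943 ± 331 in Het (SD, n = 4). All 4 KO libraries lay above all 4 Het libraries, which gave the smallest p the exact permutation test allows, 0.0286, but an adjusted p of 0.0714. A measure that reached this smallest p alone could not have passed the threshold after adjustment. Estimates were rounded before thinning, so Het 4, the shallowest library, went from 34267 detected transcripts to 34496. Thinning set equal totals, which is not equal depth over the transcripts other than the most abundant one. The most abundant transcript, of 2555 bases, took 16.9 ± 1.53% of counts in Het and 14.3 ± 1.77% in KO (SD, n = 4, exact permutation p = 0.114, adjusted 0.143). The share of the 10 most abundant transcripts, from 22.7% to 29.0% in Het and from 21.1% to 25.8% in KO, did not differ past the threshold (n = 4, exact permutation p = 0.314, adjusted 0.314).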

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

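Of 24 groups of 4 libraries examined for a library far from the others, 1 had such a library, about as many as chance gives. At equal depth KO 2 had 36727 transcripts with at least 1 count, while the other KO libraries had from 36045 to 36124. KO 2 was also the deepest library, at 19561022 estimated counts; no explanation was tested.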

How the results depend on the processing

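Alternatives that thinned counts, removed a length trend, left out abundant or read-sharing transcripts or used a data-derived covariate, and all those for units, were chosen after seeing the data. The 774 transcript calls became 3574 with DESeq2, 391 without a filter, 35 and 16 with limma on log2(TPM + 1) and log2(TPM + 0.1), and 188 with the state of 2 on/off units as covariate; the cause was not tested. Leaving out single libraries gave 60 to 454, with fewer samples in each fit. The other 8 alternatives stayed within 1.5 times, and every shared call kept its direction. In one of them, however, transcripts that share no reads were fitted alone, and the 756 calls of 3442 stand against 168 of 3368 such transcripts fitted with the rest. With the replicate block, 0 transcripts were called by edgeR (4684 at an unadjusted p under 0.05), against 852 with limma voom and 3574 with DESeq2 without it. The replicate block gave 2303 units. Correlations of same-numbered libraries ran from -0.28 to 0.15 over units, and only 3 of 8 libraries correlated best with their own number. The numbers were therefore not taken to pair samples. Unit calls stayed within 1.5 times, from 1642 to 2436, in 18 of 19 alternatives. With other transcripts added as single rows, 1258 units were called, 1245 of them among the 2276; the cause was not tested. The calls of uc008iog.1 and uc009phk.1 were lost under the block alone, those of uc007gqv.3 and uc007jqz.2 under 6 and 10 of 21 alternatives, none with a changed direction. The ratio of total counts ran from 1.15 to 1.31 with single libraries left out, and its exact permutation p fell to 0.0286 without KO 3. Alternatives needing gene names (gene lists, an Xist covariate, leaving out mitochondrial, globin and sex-linked genes) were not run. Of 2-fold transcript changes simulated above a minimum mean CPM and kept by the filter, 23.7% were recovered at these libraries' depth and spread together. The part that depth plays was not separated.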

Other observations

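Tests of read splitting, of lower abundance as finally built, of the length trend, of splits for the F-test and of the 3 libraries below were chosen after their results or related values had been seen. Tests of thinning to equal depth, of scaling without the 10 most abundant transcripts, and of splits for units and for isoform use by the Simes method were also chosen after the data were examined, though before their own results were seen; the shares with each library left out were added afterwards. Of units of 4000 to 8000 bases 18.1% rose and 14.0% fell, of those of 8000 bases or more 18.9% and 12.7%, and of those under 1000 bases 6.14% and 6.59%; differences between length classes were not tested. Of 881 units with a mean log2 CPM under 2, 99 rose and 37 fell, while of 892 at 8 or more 90 rose and 175 fell. The median log2 fold change of all units, called or not, was 0.13 in the first class and -0.06 in the last. Differences between abundance classes were not tested either. A single unit, of 5209 bases, was on in all Het libraries, at 55, 70, 55 and 22 counts, and held 0, 1, 2 and 0 counts in KO. By the same rule (at least 20 counts and 10-fold) 7 of 119 partitions of the libraries had at least 1 such unit. The genotypes made 1 of the 7, and 1 other split into 4 and 4, Het 1, KO 1, KO 2 and KO 3 against the rest, also gave 1 unit. Most partitions gave none, so such a unit is uncommon but not particular to the genotypes. Whether it exceeds chance was not tested.

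A chance division of the libraries was argued against as the source of the transcript and unit calls, by rank among splits alone. Of the 35 splits of the 8 libraries into 4 and 4, only the genotypes (1 split) gave as many as 774 transcripts, and the highest other split gave 2. The same held for the 2276 units (1 split), where the highest other gave 1. No split could rank better than 1 of 35. The other splits mix the genotypes, so a genotype difference widens the spread within their groups and lowers their counts. A technical difference that followed the genotype labels would rank first as well. Isoform use within sets was tested with edgeR's diffSpliceDGE, which called 14 of 4375 sets by the Simes method and 33 by the F-test. By the Simes method as many as 14 were called in 3 of the 35 splits, with 19 in the highest other, so chance was not excluded. By the F-test only the genotypes (1 split) gave as many as 33, but the highest other gave 31. That rank among splits was all that argued against chance. The methods differ, and no change of isoform use is claimed.

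A smaller share of transcripts than of units was called. Lower abundance as the whole reason was argued against: thinning units from a median of 192.5 to 99.9 counts, near the 99.4 of transcripts, left 21.0% called, 7.99 times the share of transcripts; a first construction, which left the median at 192.5 and gave 24.4%, was void and was replaced. Within sets, the biological coefficient of variation of a transcript was a median 3.13 times that of its set, but 1.83 times for single transcripts with the same counts in both fits, since edgeR shares information on spread between rows. Without that sharing the medians were 3.19 and 1, so reads moved between isoforms by the quantifier may account for part of the gap. Biological variation in isoform use between libraries would raise the same ratio and stays open.

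More transcripts rose than fell, 62.7% of those called, but the share varied with the fit, at 55.3% with DESeq2, 52.5% for transcripts that share no reads fitted alone, 71.8% with the data-derived covariate, and 85.7% and 87.5% with limma on log2(TPM + 1) and log2(TPM + 0.1). Deeper KO libraries were argued against, since 62.7% rose after thinning to equal depth, and 64.8% to 78.4% when each library was also left out. The part of the scaling factors cannot be told apart, since 3 other scalings, with 60.9% to 62.1%, moved the median log2 fold change by at most 0.00864. Removing the length trend of each library left 54.5%, and 56.7% to 69.5% with each library left out, against 63.0% to 75.7% uncorrected; the share was lower in all 8, so a length trend may account for part of the excess but cannot be told apart from other sources. The slopes of log2 CPM on log2 length did not separate the genotypes, for transcripts (exact permutation p = 0.143, n = 4 per genotype) or units (exact permutation p = 0.6, n = 4 per genotype). A genotype difference in long transcripts stays open. The excess also varied with abundance. At a mean log2 CPM under 2, 69 called transcripts rose and 16 fell, and at 2 to 4, 148 and 71. At 4 to 6 the numbers were 164 and 120, at 6 to 8 97 and 71, and at 8 or more 7 and 11. Differences between these classes were not tested.

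In 3 libraries, Het 2, Het 4 and KO 3, a unit of 4306 bases was on, at 246, 123 and 136 counts against 0 to 3 elsewhere, and a unit of 1801 bases was off, at 0 or 1 counts against 822 to 1117 elsewhere. It was the only one of 119 partitions of the libraries with units of both kinds (at least 20 counts and 10-fold). Exchange of single libraries between the genotypes was argued against by the first principal component of units, where KO and Het were 22.4 apart; exchange of the whole groups would leave the same gap and was not tested. Embryo sex is a candidate explanation that cannot be told apart from others here, since 2 units without gene names decide nothing.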
